A study of Mus musculus with 55 samples.

How the data were processed

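Each sample was the cytosol of 1 pyramidal neuron of the mouse prefrontal cortex, drawn through a patch pipette and made into a sequencing library from total RNA with the Nextera XT kit, per the labels' protocols. Trimmomatic, STAR and featureCounts were used on the GRCm38 build, per the submitters' processing notes; their roles, versions and settings, and whether counting used strand, are not given in the sources used here. The deposited counts are whole-number read counts per gene, in a table of 22800 gene symbols and a table of 22880 Ensembl identifiers. The authors also deposited a normalized signal table of 14067 symbols, which was found to hold the gene counts of each cell multiplied by 1 factor per cell (0.373 to 51.5, constant within a cell to a relative spread of 8.2e-16); how the factors were chosen is not given in the sources used here. Each table also held 2 columns of values that match no sample label, and these were not used. The gene counts held no entry for totals or unassigned reads, so that every library size is the sum over genes. The electrophysiology named in the study's title was not analysed here.

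Cells were grouped by the cell type, genotype and quality control labels into wild-type D1 (15), wild-type D2 (26), knockout D1 (6) and knockout D2 (7) cells. The kind and genotype written in the table headers matched the labels for each cell (0 differed). The 1 knockout D1 cell that failed quality control entered no comparison. The highest Spearman correlation between the counts of any pair of cells was 0.74 and the median 0.36, so that no library appeared to be present more than once. Total counts ranged from 260943 to 10673072 per cell among the 54 cells that passed.

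From the gene counts, CPM (each cell's counts scaled to a common total) were computed with each cell's total over genes. The difference between groups is that of the mean over cells of log2(CPM + 1), each cell weighted equally. It understates differences of genes with few reads. Where 1 group holds more cells without a read, it can far exceed the log2 ratio of mean CPM. Hprt in D1 cells, for example, differed by 3.64 at mean CPM of 193 in knockout and 138 in wild-type cells. Shares of cells with a read carry exact Clopper-Pearson intervals at 95%. Where a group had no read of a gene, the fold compares the CPM of the other group's summed counts with a floor of 3 counts over the summed total of the group without reads. No p-value was computed. The animal of each cell is not named, so each group was treated as 1 sample; cells of different ages come from different animals (5 ages in wild-type D1 and 7 in wild-type D2 cells), but no test across ages was made and within-age directions are description. Of 28 gene lists fixed before the data were examined, the members with a mean CPM of at least 1 and a read in at least 10% of the cells compared were used, over which the median difference was taken. Its percentile is the share of 10000 random lists of the same size, matched on mean expression in 20 bins, with a lower median. It is given for lists with at least 3 measured members. Random lists were drawn gene by gene, so the percentile measures spread between neither cells nor animals. A list whose members vary together from cell to cell can therefore reach an extreme percentile more easily. Dlx6os1, Xist and Tsix, named in 2 of the lists, were not among the symbols used.

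Genes named in the text were chosen by a rule fixed before the data were examined. It considers genes with a mean CPM of at least 10 in 1 of the groups compared and a read in at least 33.3% of that group's cells, and passes over mitochondrial genes and symbols of predicted genes. For wild-type D1 against D2 cells it takes the 12 largest differences per direction among genes with the same direction at each of the 4 ages shared by both kinds (29, 30, 31 and 34 days). For the knockout it takes the 10 per direction with the largest value of the smaller of the D1 and D2 differences. In each kind alone it takes the 6 per direction with the largest value of the smallest difference left when each knockout cell is left out. For knockout D1 against D2 cells it keeps the genes named for the wild-type comparison. Fmr1, Fxr1, Fxr2 and Drd1 to Drd5 are always named, with the 2 members of largest difference of each list described; for the pyramidal tract list all measured members are given. Some list members that the rule names are not reported here.

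Gene positions, merged exon lengths and overlaps between exons were taken from GENCODE vM21, an annotation of the same GRCm38 build. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9; TMM factors came from edgeR 4.0.16 in R 4.3.3. The procedure was tested on simulated data, with 200 of 22800 genes changed by 2 log2 units. For wild-type D1 against D2 cells 99% of the changed genes had the right direction, with mean estimates of 1.84 for raised and -1.99 for lowered genes. For the knockout comparisons 96.5% in D1 and 99.5% in D2 cells had the right direction. The list of raised genes lay at percentile 100 in each, and an unchanged list at 55.1, 10.6 and 90.0. Only genes with a higher mean CPM than some of the genes named here were changed. Apart from these changes and random spread, every simulated cell had the same expression profile. The real cells varied more and included gene-poor ones, so these rates need not carry over to them.

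Alternatives fixed before the data were examined were TMM factors, CPM without mitochondrial genes, a pseudocount of 10 CPM, the authors' normalized values, counts per Ensembl identifier, cells of at least 100000 counts, and thinning of each cell to 100000 counts. The log2 ratio of mean CPM, the difference of medians, other filters on low values, random lists matched on the share of cells with a read, comparison cells matched on age, the mean of the within-age differences, leaving out each age or knockout cell, and inclusion of the failed cell were fixed as well. Cells with at least 4000 genes, lists matched on transcript length in 8 bins, and the lists without mitochondrial counts, with the authors' normalized values and after thinning were added after the data were seen. So were the lists without each age or knockout cell, and in wild-type cells whose Rn18s-rs5 share was at most 4.75%, their median.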

Results

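The transcriptomes of single pyramidal neurons of the mouse prefrontal cortex were measured by patch-pipette RNA sequencing, in which the cytosol of 1 neuron is drawn into the recording pipette and made into a library. The labels divide the neurons into D1 and D2 cells, names used for dopamine receptor types; how the cells were identified is not given in the sources used here. They were taken from mice with and without the knockout of Fmr1, the X-linked gene of the RNA-binding protein FMRP, whose loss models fragile X syndrome. The labels call the cells without the knockout only that, wild-type here, and whether their strain is that of the knockout is not given in the sources used here. There were 15 wild-type D1, 26 wild-type D2, 6 knockout D1 and 7 knockout D2 cells that passed quality control per the labels. The wild-type D1 cells came from animals aged 28 to 34 days and the wild-type D2 cells from 29 to 35 days. The knockout D1 cells came from 31 and 32 days, and the knockout D2 cells from 32 days. At 32 days there were 5 of the 6 knockout D1 cells but no wild-type D1 cell, and 2 of the 26 wild-type D2 cells. Genotype and age can therefore hardly be told apart. Because no label names the animal of a cell, cells were not treated as replicates, each group was taken as 1 sample and no test was made; the SD between cells describes these cells only.

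Total counts in genes ranged from 260943 to 10673072 per cell, with medians of 2805992 in wild-type D1, 3940766 in wild-type D2, 4922872 in knockout D1 and 5712484 in knockout D2 cells. The median number of genes with a read was 6047, 4990, 6486 and 6706 in the same order. A read in at least 4000 genes was found in 9 of 15 wild-type D1, 13 of 26 wild-type D2, 6 of 6 knockout D1 and 6 of 7 knockout D2 cells, called gene-rich cells from here on. The mitochondrial share of counts reached 44.8% in a wild-type D1 cell, against at most 3.72% among the knockout D1 cells. The ribosomal RNA gene Rn18s-rs5 took a median of 1.88% of counts in wild-type D1 and 6.17% in wild-type D2 cells, and the 10 highest genes 8.88% and 13.3%. The median over measured genes of the knockout difference was 0.98 in D1 and 0.56 in D2 cells on the log2(CPM+1) scale. With knockout D2 cell 5 alone left out, the median in D2 cells was 0.85. In gene-rich cells the medians were 0.14 in D1 and -0.39 in D2 cells. Between wild-type D1 and D2 cells the median was -0.14, and -0.50 in gene-rich cells. Gene lists are therefore described relative to random lists of genes of like expression from the same comparison.

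**Figure D1:**
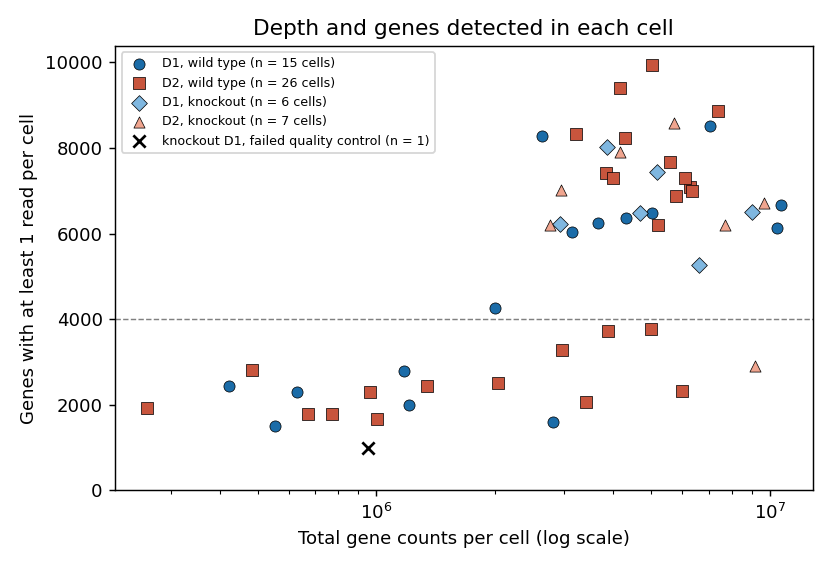
Genes with at least 1 read against total gene counts (log scale) for each cell, by group; the dashed line marks 4000 genes. Gene-poor cells below the line were found in both wild-type groups (6 D1 and 13 D2 cells), in 1 knockout D2 cell and in the knockout D1 cell that failed quality control.

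Fmr1 (chromosome X, 68678541 to 68717963, GRCm38) had reads in 8 of 15 wild-type D1 cells (53.3%, exact 95% interval 26.6 to 78.7%) and 13 of 26 wild-type D2 cells (interval 29.9 to 70.1%). It had no read in any of the 6 knockout D1 cells (upper bound 45.9%) or the 7 knockout D2 cells (upper bound 41%), which bounds the share of cells with a read and not of cells that express the gene. Among gene-rich wild-type cells it was detected in 8 of 9 D1 and 10 of 13 D2 cells. Mean Fmr1 was 70 ± 99.6 CPM (SD, n = 15) and 41.1 ± 77.5 CPM (SD, n = 26) in wild-type D1 and D2 cells. In the summed counts of each group it had 121 and 62.8 CPM, at least 1306-fold and 882-fold above the floor of 3 counts over all knockout cells of the same kind. The intervals treat cells as independent draws, which cells of the same animal may not be, so they describe these cells only. Floors cover counting error only, since the reads were amplified and carried no molecular identifiers. The paralog Fxr1 was detected in 9 of 15, 15 of 26, 5 of 6 and 3 of 7 cells, and Fxr2 in 9 of 15, 14 of 26, 4 of 6 and 6 of 7 cells, of wild-type D1, wild-type D2, knockout D1 and knockout D2. The knockout difference of Fxr1 was 0.99 in D1 and 0.34 in D2 cells, and that of Fxr2 0.68 and 2.39; in gene-rich cells all 4 values were below 0, between -0.30 and -1.32. As each knockout cell was left out, Fxr1 ranged from 0.61 to 1.75 in D1 cells (without cells 6 and 3). Without knockout D2 cell 2 or 6 it stood at -0.41 or -0.46 in D2 cells, and Fxr2 ranged from 0.18 to 1.41 in D1 cells as each cell was left out.

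Dopamine receptor genes were sparse in the counts. Drd1, the D1 receptor gene, had reads in 4 of 15 wild-type D1 cells (59.0 ± 114 CPM, SD) and 2 of 26 wild-type D2 cells (5.07 ± 25.5 CPM), but in 0 of 6 knockout D1 cells and 3 of 7 knockout D2 cells (30.6 ± 44.2 CPM). Drd2, the D2 receptor gene, had no read in any cell, nor had Drd3 and Drd4, which in the 26 wild-type D2 cells allows a share of cells with a read of up to 13.2% and sets no bound on expression. Reads of Drd5 were found in 9 of 15 wild-type D1 and 18 of 26 wild-type D2 cells at a mean of 5.08 ± 10.8 and 8.56 ± 22.7 CPM (SD), and in 1 of 6 and 2 of 7 knockout cells with 1 and 4 counts in all. An antisense transcript shares 1531 of the 3152 exon bases of Drd5, and the library kit does not mark strand. The cell kinds were therefore taken from the labels alone.

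Wild-type D1 and D2 cells were compared to ask which transcripts differ between the 2 kinds of pyramidal neuron. A pipette sample could also hold RNA of other cell types. In wild-type D1 cells the mean log2(CPM+1) was 3.36 ± 2.49 over microglia and 4.26 ± 1.41 over general pyramidal markers (SD, n = 15). Differences in markers of other cell types, in any comparison here, need therefore not lie in the neurons, and this was not tested. The largest differences toward D1 cells, among genes higher in D1 at each of the 4 shared ages, were in C1qa, a chain of complement C1q made by microglia (358 ± 553 CPM, SD, n = 15, against 21 ± 65.6 CPM, n = 26; difference 3.68 log2 units), Smox, spermine oxidase (383 ± 1134 against 6.36 ± 21.5 CPM; 3.55), and Camk2d, the delta subunit of calcium/calmodulin kinase II (440 ± 947 against 164 ± 826 CPM; 3.20). Il1rapl2, an X-linked synaptic receptor of the interleukin-1 receptor family, had reads in 6 of 15 D1 cells and 0 of 26 D2 cells (91.0 ± 181 CPM; 91.4 CPM in summed counts, at least 2921-fold higher than the floor of 3 counts over all D2 cells). Toward D2 cells, leaving aside Grcc10 (-2.74), whose exons overlap another transcript, the largest were Pmm1, a phosphomannomutase (96.2 ± 155 in D1 against 371 ± 479 CPM in D2; -3.22), Reep1, which shapes the endoplasmic reticulum in axons (154 ± 392 against 441 ± 948 CPM; -2.89), and Sorcs1, a sorting receptor of the sortilin family (5.93 ± 17.4 against 91.8 ± 153 CPM; -2.73). Without the cells of 30 days C1qa differed by 2.40 and Smox by 2.31, and without those of 29 days Sorcs1 by -1.68. Of the genes that may be named, 377 were higher in D1 and 307 in D2 cells at each of the 4 ages, against 7860 measured. The shared direction is a filter here and not evidence for a difference, since random directions at 4 ages would also agree for many genes. C1qa lies on chromosome 4 at 136895917 to 136898803 and Pmm1 on chromosome 15 at 81951108 to 81960930 (GRCm38).

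Further genes higher in D1 cells were the GTPase-activating protein gene Arhgap5 (3.17), Sra1 (3.15), the endosomal sorting nexin Snx5 (3.11), the mitochondrial deacetylase Sirt3 (2.99), Hypk (2.95), the phospholipid flippase Atp8a1 (2.93), Tbc1d10a (2.85) and the adhesion molecule Cntn4 (2.78). Genes higher in D2 cells included Fgf9, a secreted growth factor read in 1 of 15 D1 and 13 of 26 D2 cells (-2.65), and Neto1, an auxiliary subunit of kainate receptors (-2.63). The mitochondrial import chaperone Timm10 (-2.60), the matrix protein Spon1 (-2.51), the histone demethylase Kdm3a (-2.50), the adhesion molecule Emb (-2.45) and Lpgat1 (-2.43) lay in the same direction. Without the cells of 29 days Fgf9 stood at -1.75 and Spon1 at -1.38. Grcc10 (-2.74) and Atn1 (-2.44) were also higher in D2 cells, but both share exons with a read-through transcript and are uncertain, as are Hypk, Snx5, Sirt3 and Emb (686 of 2923 exon bases), which overlap genes on the other strand. Neto1, Sorcs1 and Atp8a1 share 219, 213 and 66 exon bases with antisense transcripts. Each of the 24 named genes kept its sign in gene-rich cells. These are among the cells that chose the genes, so a kept sign was likely beforehand. There C1qa differed by 1.52, Pmm1 by -1.57, Sra1 by 1.79, Hypk by 1.48, Cntn4 by 1.33 and Atp8a1 by 1.12. Snx5 differed by 0.85, Grcc10 by -0.50 and Atn1 by -0.48, while others such as Smox (4.18) and Sorcs1 (-5.62) grew. The SD between cells within a group was of the same order as these differences, for example 4.48 for C1qa in D1 cells on the log2 scale. The side label of the cells split them exactly as their kind, so that side and kind cannot be told apart.

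Markers of layer 5 pyramidal tract neurons, which project out of the cortex to the brainstem and spinal cord, were lower in wild-type D1 than D2 cells for 10 of 11 measured members. Their median difference was -1.47, at percentile 0 of 10000 random lists. Bcl11b (Ctip2), a transcription factor of corticospinal neurons, had 27.5 ± 63.8 CPM in D1 and 128 ± 178 CPM in D2 cells (SD; -3.08), and Npr3, the natriuretic peptide clearance receptor, 5.16 ± 19.5 and 38.2 ± 57.6 CPM (-2.05). The other members were Pou3f1 (-1.81), Parm1 (-1.70), Sulf2 (-1.49), Crym (-1.47), Bcl6 (-1.09), Ldb2 (-0.76), Fezf2 (-0.51), Npnt (-0.12) and Diaph3 (0.48). The list lay below the median of all measured genes at 29, 30 and 34 days, and above it by 0.38 at 31 days, where 3 cells of each kind were compared. Without the cells of 29 days it lay at percentile 0.17, with Pou3f1 at -0.56, Npr3 at -1.09 and Bcl6 at -0.35; Fezf2, Ldb2, Npnt and Diaph3 moved by over 1.5 times with 1 age or another left out, and Npnt (0.60) and Diaph3 (-0.12) changed sign, without 29 and 31 days. In gene-rich cells the mean over the members was 3.34 ± 1.77 in D1 (SD, n = 9) and 5.62 ± 0.87 in D2 cells (SD, n = 13). Markers of intratelencephalic and upper-layer neurons (percentile 65) and of layer 6 and near-projecting neurons (52.3) lay inside the central range of the random lists, and at 85 and 85.4 in gene-rich cells. Within the intratelencephalic list, Lamp5 was lower (-3.42) and Rorb, a layer 4 transcription factor, higher (1.41, and 0.56 without the cells of 29 days) in D1 cells.

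**Figure D2:**
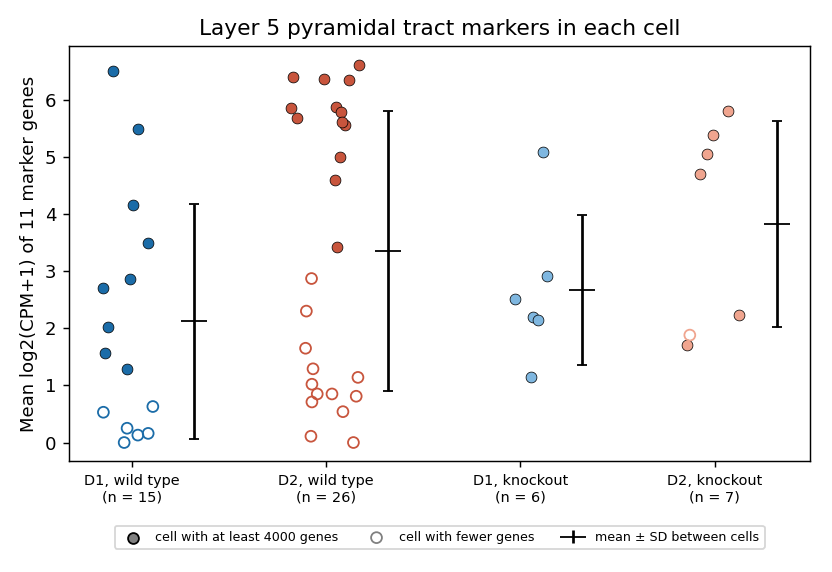
Mean log2(CPM+1) over the 11 pyramidal tract markers measured in wild-type cells, for each cell of the 4 groups; filled points are cells with at least 4000 genes, and bars give the mean and SD between cells. The group means were 2.12 and 3.36 in wild-type D1 and D2 cells, and 2.67 and 3.82 in knockout D1 and D2 cells, with wide overlap.

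GABA receptor genes were lower in wild-type D1 cells for 12 of 13 members (median -0.80, percentile 1.83), among them Gabrb1 (reads in 7 of 15 against 16 of 26 cells; -1.56). Transcripts bound by FMRP in textbook accounts were lower for 29 of 43 members (median -0.51, percentile 1.24), including Mtor (-2.18) and the spectrin Sptbn1 (-2.07). Sodium, HCN and calcium channels (percentile 3.13, with Trpc4 at -2.32) and glutamate receptors (4.73, with Grin1 at -1.85 and Gria3 at -1.58) lay at percentiles 0 and 0.1 in gene-rich cells. Microglia markers were higher in D1 cells for 11 of 12 members (median 0.85, percentile 99.8), led by C1qa and Aif1 (2.18), but lay above all measured genes only at 30 and 34 days. Cytosolic ribosomal protein genes were higher for 59 of 81 members (median 0.53, percentile 100), with Rplp0 at 2.57 and Rps26 at -2.19. Among lists matched on transcript length as well, the GABA receptors lay at percentile 3.29 and the FMRP targets at 10.3. With the authors' normalized values the GABA receptors lay at percentile 5.87. Of the 4 shared ages, the GABA receptors and the channels lay below all measured genes at 3, the FMRP targets and glutamate receptors at 2, and the ribosomal proteins above at 3. Without the cells of 29 days the GABA receptors lay at percentile 11, the FMRP targets at 5.61, the channels at 26.1 and the glutamate receptors at 42.3, with Grin1 at -0.05, Gria3 at -0.76 and Gabrb1 at -0.51. Without those of 30 days the microglia markers lay at 82.3, the GABA receptors at 9.22 and the ribosomal proteins at 95.3, with Aif1 at 1.29 and Rps26 at -3.51, and without those of 34 days the FMRP targets at 13.9, with Sptbn1 at -1.27.

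Knockout and wild-type cells were compared within each kind to ask what the loss of Fmr1 changes. Besides Fmr1 itself (-3.22 in D1, -2.53 in D2 cells), the genes lowest in both kinds of knockout cell were led by Acly, ATP citrate lyase, which makes cytosolic acetyl-CoA. Its reads were found in 1 of 6 knockout against 7 of 15 wild-type D1 cells (17.9 ± 43.9 against 122 ± 246 CPM, SD; -2.34), and in 1 of 7 against 16 of 26 D2 cells (0.025 ± 0.0662 against 75.8 ± 180 CPM; -3.42). Kcng1, a modulatory potassium channel subunit, differed by -2.32 in D1 and -2.60 in D2 cells. Glul, the glutamine synthetase that is abundant in astrocytes, differed by -2.27 and -2.05 (-1.36 in D2 without knockout D2 cell 3). In the summed D2 counts, however, Glul was not lower, at 203 CPM in knockout and 197 CPM in wild-type cells. Rnf217, a ubiquitin ligase, was highest by the naming rule toward the knockout (chromosome 10, 31493193 to 31609184), at 156 ± 157 against 49.6 ± 133 CPM in D1 (SD; 4.44) and 120 ± 119 against 12.1 ± 28.1 CPM in D2 cells (4.41).

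Other genes higher in both kinds of knockout cell were Dffa, the inhibitor of the apoptotic nuclease (4.59 in D1, 4.0 in D2), Mllt4, the junction protein afadin (4.84, 3.97), and Zfc3h1, a factor in nuclear RNA decay (3.96, 3.69). Mapk9, the stress kinase JNK2, was higher by 6.11 and 3.67, although its mean in D2 cells was lower in the knockout (178 ± 155 against 255 ± 816 CPM, SD). The purine salvage gene Hprt was higher by 3.64 and 3.62, although in the summed D1 counts it was lower in the knockout (193 against 293 CPM). Tmem191c (4.39, 3.67), the dynein subunit Dync1li1 (3.90, 3.62), Fam168a (3.63, 3.56) and Lancl1 (3.54, 3.90) completed that side. Toward lower values stood the Myc antagonist Mxi1 (-3.19, -1.94), Teddm2 (-1.99, -1.90), Tmx1 (-1.91, -1.90), the glycosylation enzyme subunit Ddost (-2.23, -1.89), cyclin E1, Ccne1 (-1.90, -1.83), and Sgta (-1.82, -2.15). Against wild-type D2 cells of 31 and 32 days alone Sgta differed by 0.05. Without knockout D1 cell 5 it stood at -1.01 and Ddost at -3.53 in D1 cells, without cell 6 Sgta at -1.07, and without cell 1 Tmx1 at -3.14. Glul and Teddm2 overlap by 67 exon bases on opposite strands, so that their reads cannot be fully told apart. Tmem191c shares 477 of 1631 exon bases with another transcript of its strand, and Mxi1 194 and Fxr1 178 with genes on the other strand, which leaves part of their counts uncertain. All 20 genes named for both kinds kept their sign in gene-rich cells, with smaller differences for genes such as Tmem191c (1.26, 0.27) and Lancl1 (0.92, 0.91). Since those cells are among the ones that chose the genes, a kept sign was likely beforehand and says little about stability. Across 13025 genes the 2 knockout differences, which share no cells, had Pearson r 0.16 and Spearman rho 0.17, and -0.07 and -0.06 in gene-rich cells; genes are not independent replicates.

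In D1 cells alone, the naming rule gave Taf2, a subunit of the transcription factor TFIID, at 194 ± 98.9 CPM in the 6 knockout cells against 1.64 ± 5.77 CPM in the 15 wild-type cells (SD; 7.00). It was followed by the polarity gene Llgl1 (6.45), Tmem9 (6.37), the protein kinase A anchor Akap13 (6.27), Cpeb1, which binds messenger RNA and controls its polyadenylation (6.23), and Mapk9. Toward lower values in knockout D1 cells stood the zinc finger gene Zfp30 (0.0756 ± 0.185 against 606 ± 1341 CPM; -4.46), C1qa (-3.92) and the disulfide isomerase Pdia3 (-3.74), with Gng10 at -3.54. Emc3, part of an insertase of the endoplasmic reticulum (-3.50), and Zfp37 (-3.37) had no read in the 6 knockout cells. Each had reads in 8 of the 15 wild-type cells, so many wild-type cells had no read either. Their 174 and 140 CPM in the summed wild-type counts were at least 1870-fold and 1502-fold above the floor of 3 counts over the knockout group. Gng10 shares 946 of its 1192 exon bases with a read-through transcript and is uncertain, and Llgl1 and Pdia3 share 44 and 18 with genes on the other strand.

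Since the median measured gene was itself higher by 0.98 in knockout D1 cells, list members are counted here against that median. FMRP targets lay above it for 36 of 43 members (median 2.37, percentile 99.9), led by Herc2, a ubiquitin ligase (368 ± 202 against 78.7 ± 126 CPM, SD; 5.06) and the calcium-activated potassium channel Kcnma1 (4.93). Glutamate receptors lay above it for 15 of 20 members (median 2.40, percentile 99.8), with Grm7 at 4.48 and Gria3 at 3.99. Sodium, HCN and calcium channels did so for 22 of 29 (median 2.26, percentile 99.4), with Cacnb2 at 5.46 and Nalcn at 5.03. Autism-associated genes lay above for 24 of 33 (median 2.20, percentile 98.8, Kmt2c at 4.43), and mGluR, ERK and mTOR signalling genes for 21 of 34 (median 1.97, percentile 97.8), including Tsc2 (4.59) and Homer1 (4.53). Cytosolic ribosomal proteins lay below for 71 of 81 members (median -0.28, percentile 0), with Rplp1 at -3.28 and Rpl7a at -3.03. The nuclear-encoded respiratory chain lay at percentile 0 (median 0.32, 53 of 74 below, with Ndufs1 at 3.18 and Sdhb at 3.03), and mitochondrially encoded genes at percentile 0 (median -0.94, 14 of 15 below). Microglia markers lay at percentile 0.05 (10 of 12 below, Tyrobp at -2.95) and hemoglobin and other erythroid markers at 1.34 (4 of 4 below). The wild-type D1 cells are shared with the D1 against D2 comparison, where they were high in C1qa, microglia markers and ribosomal proteins and low in FMRP targets, channels and glutamate receptors. In gene-rich cells the mean over FMRP targets was 5.32 ± 1.24 in wild-type D1, 6.65 ± 0.40 in wild-type D2, 6.68 ± 0.50 in knockout D1 and 5.93 ± 1.16 in knockout D2 cells (SD), so that the wild-type D1 cells lay lowest. In D1 cells the knockout difference was larger for longer transcripts (Spearman rho 0.26 across genes). With lists matched on length too, the FMRP targets lay at percentile 58.5, the autism-associated genes at 60.1, the signalling list at 81.6, the channels at 84.6 and the glutamate receptors at 93.4. The respiratory chain lay at 16 and the erythroid markers at 5.62 among those lists, while microglia markers (1.13), mitochondrially encoded genes (0.05) and ribosomal proteins (0) stayed at the bottom. In gene-rich cells the signalling list lay at 72 and mitochondrially encoded genes at 67.9. Without knockout D1 cell 5 the signalling list lay at percentile 74.1, the autism-associated genes at 91.5 and the channels at 96.8, and without cell 2 the erythroid markers at 3.12.

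In D2 cells alone, the naming rule gave toward the knockout Mrpl57, a protein of the mitochondrial ribosome (259 ± 212 CPM in the 7 knockout against 31.3 ± 59.6 CPM in the 26 wild-type cells, SD; 5.28), and the centrosomal Cep19 (211 ± 134 against 55.3 ± 137 CPM; 5.03). The splicing factor Isy1 (5.01), the apoptosis inhibitor Birc6 (4.97), Dus3l (4.72) and the retromer subunit Vps29 (4.61) followed. In gene-rich cells Mrpl57 stood at 3.42, Cep19 at 3.34, Isy1 at 4.16, Birc6 at 1.87, Dus3l at 2.93 and Vps29 at 1.88. Toward lower values, apart from Acly, stood utrophin, Utrn (0.122 ± 0.254 against 113 ± 215 CPM; -3.39), Chgb, a protein of secretory granules (-3.28), the actin regulator Flii (-3.04, no read in 7 knockout cells; 160 CPM in the summed wild-type counts, at least 2249-fold above the floor), Hnrnpa1 (-3.01) and Smpdl3a (-2.91). Flii had reads in 12 of the 26 wild-type cells, so many wild-type cells had no read of it either. Hnrnpa1 and the ribosomal protein genes have processed pseudogenes, which makes their counts uncertain. Exons overlap those of other genes for 660 bases in Isy1, 611 in Birc6, 340 in Vps29 and 44 in Flii.

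In D2 cells members are counted against the median of 0.56 in the same way. Cytosolic ribosomal proteins lay above it for 73 of 81 members (median 1.44, percentile 99.8), led by Rpl22l1 (3.43) and Rps24 (3.15). The nuclear-encoded respiratory chain lay above for 58 of 74 (median 1.43, percentile 98.3), with Ndufs8 of complex I at 343 ± 173 against 163 ± 276 CPM (SD; 4.11) and Sdhd at 3.74. Astrocyte markers lay below for 9 of 10 members (median -0.51, percentile 0.0900), led by clusterin, Clu (51.2 ± 118 against 590 ± 1174 CPM; -2.87), and lay at percentile 35.8 in gene-rich cells. The 3 measured vascular markers lay at percentile 0.400, with Bsg at 1.30 and Acta2 at -0.90, and at 2.59 in gene-rich cells. Mitochondrially encoded genes lay at percentile 1.68 over all cells and at 100 in gene-rich cells. The mitochondrial share of counts reached 16.6% in a knockout and 29.3% in a wild-type D2 cell. The FMRP targets lay at percentile 65.9 (27 of 43 members above, median 1.06) and at 8.53 in gene-rich cells, with Ubqln2 at 2.91 and Arc at -2.61. Among lists also matched on length the ribosomal proteins lay at percentile 95.5 and the respiratory chain at 96.9, and in gene-rich cells both lay at 100. Pyramidal tract markers lay at percentile 28.8 over all cells and at 0.310 in gene-rich cells. In the test without single knockout cells the ribosomal proteins and the respiratory chain moved further. Without knockout D2 cell 2 these 2 lists lay at 67.3 and 68.9 and mitochondrially encoded genes at 31.2, and without cell 5 the respiratory chain lay at 88.5.

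Knockout D1 and D2 cells were compared to ask whether the 2 kinds differ in the knockout as they do without it. Pyramidal tract markers were again lower in D1 cells, for 9 of 10 members (median -1.16, percentile 0.490). Bcl11b had 28.0 ± 43.5 CPM in D1 (SD, n = 6) and 186 ± 185 CPM in D2 cells (n = 7; -3.41), Sulf2 differed by -2.13, Npr3 by -1.83, Parm1 by -1.66, Pou3f1 by -1.22, Ldb2 by -1.10, Stac by -1.08, Bcl6 by -0.76 and Crym by -0.25, while Fezf2 stood at 0.25. The list lay at percentile 2.64 without knockout D2 cell 6. Immediate early genes, which neurons switch on with activity, were higher in D1 cells for 14 of 16 members (median 3.06, percentile 100). Arc, a synaptic plasticity gene, had 1212 ± 1123 CPM in D1 and 38.4 ± 89.1 CPM in D2 cells (7.48), and the transcription factor Npas4 442 ± 326 and 43 ± 79.6 CPM (4.75).

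Of the 24 genes named for the wild-type comparison, 13 had the same sign in knockout cells, 8 of 12 toward D1 and 5 of 12 toward D2. Atp8a1 (3.51), Sirt3 (3.25), Smox (2.56) and Sorcs1 (-2.41) were among those with the same sign, and Reep1 (4.41) and Kdm3a (2.38) among those with the opposite sign. Across 13025 genes the wild-type and knockout differences between D1 and D2 cells had Pearson r and Spearman rho of -0.01, with 45.7% of genes of the same sign. Cytosolic ribosomal proteins, higher in D1 among wild-type cells, were lower in D1 among knockout cells for 74 of 82 members (median -1.40, percentile 0), with Rpl7a at -6.15. The respiratory chain was lower for 69 of 76 (median -1.18, percentile 0), with Sdhd at -3.61. The 4 measured GABAergic interneuron markers lay at percentile 0.110, with Gad1 at 0.143 ± 0.350 against 21.1 ± 28.9 CPM (SD; -2.36) and Gad2 at -2.35 and without a read in D1 cells. Oligodendrocyte markers lay at percentile 1.41 (Mobp at -2.93, Mbp at -1.95) and at 15.3 in gene-rich cells. FMRP targets lay at percentile 99 (34 of 43 higher) and autism-associated genes at 97.9 (24 of 33 higher, Bcl11a at 3.37), and at 61.6 and 71 among lists also matched on length. As each knockout cell was left out, the oligodendrocyte markers ranged from percentile 0.05 (without D1 cell 4) to 15.3 (D2 cell 5), the autism-associated genes down to 87.4 (D1 cell 5), the FMRP targets down to 95.2 (D2 cell 2) and the interneuron markers up to 3.86 (D2 cell 7). The knockout cells came from 31 and 32 days alone, and animal and group cannot be told apart.

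**Figure D3:**
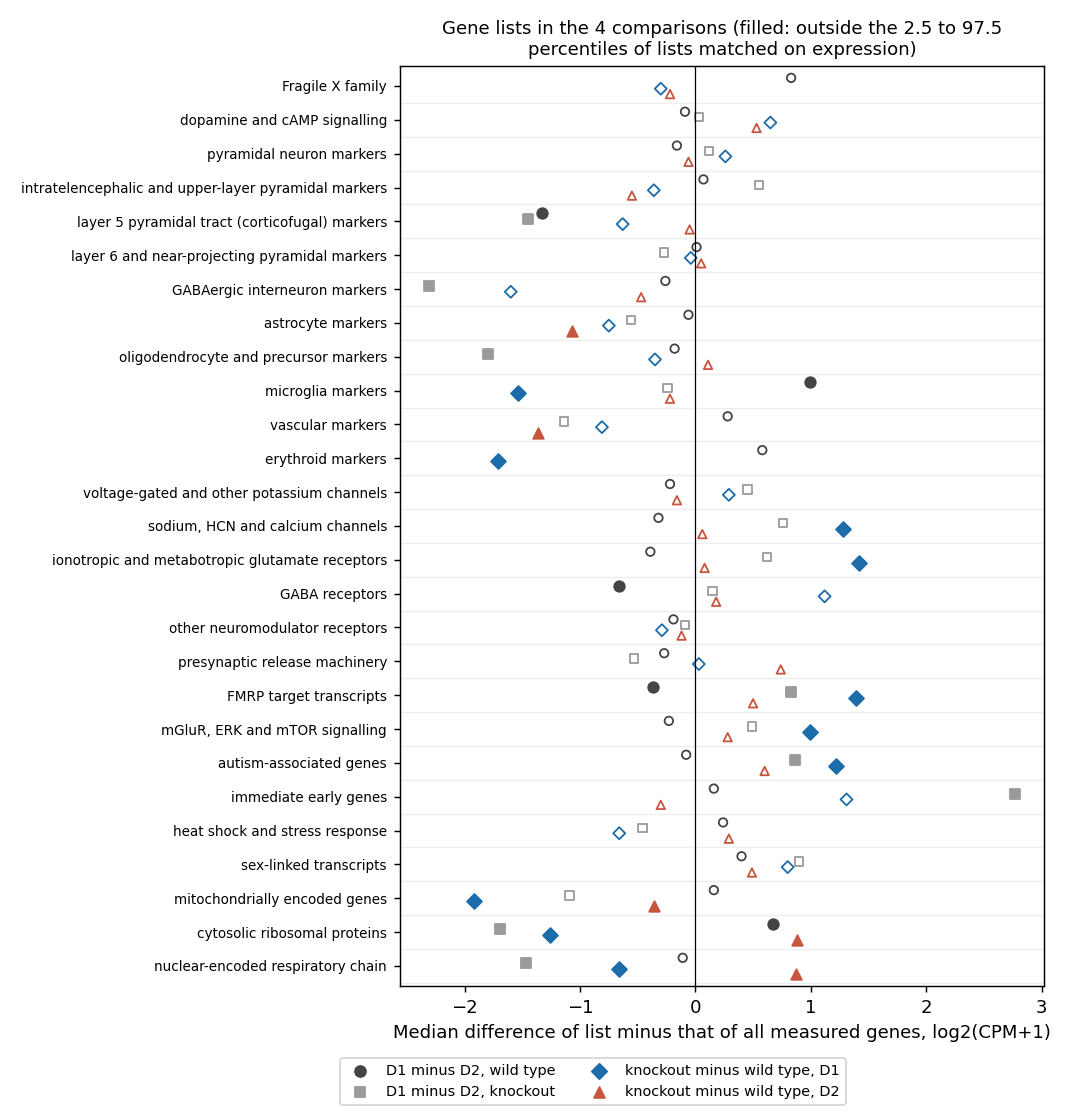
Median difference of each gene list minus the median of all measured genes, in log2(CPM+1), for the 4 comparisons, with filled symbols outside the central 95% of random lists matched on expression. Pyramidal tract markers lay to the left in both D1 minus D2 comparisons (-1.33 and -1.45), and immediate early genes far to the right among knockout cells (2.77).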

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

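The values in this part follow from rules set before the data were examined, and no test of a cause was made for them. Within the knockout groups of 6 and 7 cells, the highest or lowest cell was compared with the nearest other cell relative to the range of the group. Of 128 such comparisons 24 found a cell standing apart, and in 13 of the 24 all other cells had no read. Chance finds about 1 in 20 for values without an excess of zeros; many of these genes were named for few reads in knockout cells, so that the number found cannot be set against chance.

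Among knockout D1 cells, cell 6 had a mean of 7.57 over layer 6 and near-projecting markers, against at most 2.40 in the others, and cell 3 a mean of 5.87 over mitochondrially encoded genes, against at least 7.56. Cell 2 had no read of Dffa (0.00, against at least 6.21) and was the sole knockout D1 cell with reads of Acly (6.76), Mxi1 (6.30), Ccne1 (1.50) and Pdia3 (4.05), in log2(CPM+1). Cell 1 alone had reads of Kcng1 (1.43), Tmx1 (7.43) and C1qa (6.66), cell 5 alone of Zfp30 (0.54), and cell 6 alone of Gng10 (6.52).

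Among knockout D2 cells, cell 5 had 2904 genes with a read, against at least 6194 in the others, and no read of Rnf217 (0.00, against at least 5.05). Cell 2 had a mean of 2.88 over erythroid markers, against at most 0.31, and alone had reads of Hnrnpa1 (3.62). Cell 3 was low in Tmem191c (2.95, against at least 7.69) and alone had reads of Ccne1 (3.27). Cell 1 alone had reads of Acly (0.23) and stood above the others in Kcng1 (2.80, next 0.57) and Tmx1 (4.30, next 1.06). Cell 4 stood above the others in Mxi1 (4.52, next 1.26) and Utrn (0.75, next 0.23), and cell 6 alone had reads of Smpdl3a (0.72).

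The knockout difference of Llgl1 was 6.45 in D1 and -1.66 in D2 cells, which is 8.11 apart, with every knockout D1 cell above and every knockout D2 cell below the mean of the wild-type cells of its kind. That difference was not tested. In the knockout D1 cell that failed quality control, the ribosomal RNA gene Rn18s-rs5 took 59.5% of 950010 counts, against at most 31.8% in the cells that passed, and 995 genes had a read.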

How the results depend on the processing

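Gene-rich cells, lists matched on length, and lists without mitochondrial counts, with the authors' normalized values, after thinning, without 1 age or knockout cell or in cells of low ribosomal RNA share were chosen after the results were seen; the other alternatives were fixed before. Of 7480 values recomputed for 453 results, 7367 moved by less than the SD between cells (or, for correlations, the spread when knockout cells were left out) without a counted change of sign, 101 moved further, and 12 changed sign. A change of sign was counted only for genes named by the rules of largest difference, lists outside the central 95%, medians and correlations; others, such as Fxr1 and Fxr2 in gene-rich cells, were not counted so. Of the 101, 45 came from the log2 ratio of mean CPM and 31 from the difference of medians. That spread is wide, so staying within it is a weak condition. TMM factors, counts without mitochondrial genes, counts per Ensembl identifier, thinning and the failed cell moved no result past that spread. Requiring 100000 counts removed no cell and tests nothing.

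With the log2 ratio of mean CPM, Mapk9 in D2 cells changed to -0.51 and the median knockout difference in D2 cells to -0.10, since the mean CPM follows the few cells with the highest values. With wild-type D2 cells of 31 and 32 days, Sgta stood at 0.05; the cause was not tested. The median difference between wild-type D1 and D2 cells was 0.04 as the mean of the 4 within-age differences and ranged from -0.39 to 0.05 when each age was left out, so its sign is not settled; the cause was not tested. In gene-rich cells the median knockout difference in D2 cells was -0.39, the correlation of the 2 knockout differences -0.07 and that of the D1 against D2 differences -0.07; choosing cells by genes with a read moves such medians by construction, and the cause was not tested for the correlations. Over genes with a mean CPM of at least 10 in all 4 groups the correlation of the knockout differences was 0.03; the cause was not tested. When each knockout cell was left out it ranged from 0.09 to 0.21.

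Relative to all measured genes, mitochondrially encoded genes changed sign in gene-rich cells, to 0.12 for the knockout difference in D1 and 1.60 in D2 cells. Without a filter on low values they stood at 0.20 in D2 cells and the nuclear-encoded respiratory chain at 0.29 in D1 cells. As each knockout cell was left out they ranged from -0.80 to 0.15 in D2 cells, above 0 without cell 2. The unfiltered median of all genes is at 0 by construction, as many genes have no read. No paired analysis was possible because replicate numbers only count cells within a group and no label pairs cells; wild-type differences within the 4 shared ages were taken instead, without a test. Depth limits detection most in gene-poor cells, and a gene without a read was not detected, which does not show that it is absent.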

Other observations

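The test of thinning, the test of length matching for the D1 knockout pattern as a whole and for the pyramidal tract markers, and the test of ages were set before their results were seen; the tests in gene-rich cells, in cells of low ribosomal RNA share, in D2 or knockout cells and of single lists were chosen after. Of the lists not described so far, voltage-gated and other potassium channels lay at percentile 6.13 between wild-type D1 and D2 cells, with the beta subunit Kcnab1 at 118 ± 287 against 4.78 ± 14.1 CPM (SD; 2.34) and the SK channel Kcnn2 at 118 ± 201 against 398 ± 529 CPM (-2.18). In the knockout they lay at 79.1 in D1 and 17.4 in D2 cells. Dopamine and cAMP signalling genes lay at percentile 30.9 in wild-type cells, and at 80.8 and 77 for the knockout difference in D1 and D2 cells, where the inhibitory G protein Gnai1 stood at 4.22 and 3.33. Among them the phosphodiesterase Pde4b stood at 4.59 in D1 cells (268 ± 284 against 24.3 ± 50.3 CPM, SD), and Pde2a at 3.37 in D2 cells. Presynaptic release genes lay at 11.7 in wild-type cells and at 12.4 in knockout cells between D1 and D2, where the complexin Cplx1 was lower in D1 cells in both (-1.89 and -4.17); in gene-rich cells the list lay at 67.6 and 44.2.

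Other neuromodulator receptors lay at percentile 14 in wild-type cells, with the serotonin receptor Htr1b at -1.58 and the neuropeptide Y receptor Npy1r at 1.10. For the knockout difference they lay at 30.9 in D1 cells, with the cannabinoid receptor Cnr1 at 3.54, and at 64.3 in D2 cells, with Htr1f at 2.84. The stress response list lay at 77.3 in wild-type cells, where the stress factor Ddit3 was lower in D1 cells (4.39 ± 7.75 against 77.7 ± 127 CPM, SD; -2.36). Among knockout cells Grm2, a presynaptic glutamate receptor, had reads in 4 of 6 D1 and 0 of 7 D2 cells, at 308 CPM in the summed D1 counts, at least 4332-fold above the floor of 3 counts over the D2 group. General pyramidal markers lay at 28.9 in wild-type cells and at 81.8 in gene-rich ones, with Neurod6 at 1.63 (0.84 without the cells of 30 days) and Camk2b at -1.34. The Y-linked Eif2s3y had reads in 9 of 15 wild-type D1, 13 of 26 wild-type D2, 6 of 6 knockout D1 and 4 of 7 knockout D2 cells. Immediate early genes lay at percentile 97.0 for the knockout difference in D1 cells and at 7.26 in D2 cells, with Arc at 4.63 and -2.61, and at 78.9 in D1 cells without knockout D1 cell 4. The difference between those values was not tested.

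Most measured genes had higher values in knockout cells than in wild-type cells of the same kind, with a median difference of 0.98 in D1 and 0.56 in D2 cells. For D1 cells lower depth in the wild-type cells is argued against, since with every cell thinned to 100000 counts the D1 median was 0.92. That test was set for D1 cells alone. With gene-rich cells alone the median difference was 0.14 in D1 and -0.39 in D2 cells, but choosing cells by genes with a read moves this median by construction. Across cells, the number of genes with a read and the mean over measured genes had a Spearman rho of 0.97. The shift and the smaller share of gene-poor cells in the knockout are thus nearly the same measure. Neither can be tested as the source of the other with these values. The cause of the general shift, including a difference between animals or recording days, stays open.

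In D1 cells FMRP targets, glutamate receptors and ion channels lay at the top of the knockout difference, and ribosomal and respiratory chain genes at the bottom. Gene-poor wild-type libraries are argued against, as the FMRP targets lay at percentile 100 and the ribosomal proteins at percentile 0 in gene-rich cells. Among lists matched on length the ribosomal proteins stayed at percentile 0, but the length bins are coarse for such short transcripts. A transcript length trend behind the whole pattern can therefore not be excluded by this test. For single lists such a trend may account for the FMRP targets (percentile 99.9 to 58.5) and the glutamate receptors (99.8 to 93.4). It may also account for the channels (99.4 to 84.6) and the respiratory chain (0 to 16). An effect of FMRP loss that is alike in both kinds cannot be told: in D2 cells the FMRP targets lay at percentile 65.9 and at 8.53 in gene-rich ones, and the ribosomal proteins and respiratory chain at 99.8 and 98.3, but at 67.3 and 68.9 without knockout D2 cell 2 and at 95.5 and 96.9 among lists matched on length. Age, animal, an effect of the knockout on D1 cells alone, and low values of the FMRP targets in the shared wild-type D1 cells were not tested and stay open.

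Pyramidal tract markers were higher in D2 than D1 cells in both genotypes, whose cells are not shared. Gene-poor libraries are argued against by percentile 0.0700 in gene-rich wild-type cells, a length trend by percentile 0 among length-matched lists, and cells of a single age by the same direction at 3 of the 4 shared ages. A difference in ribosomal RNA share is argued against by percentile 0 in wild-type cells with a share of at most 4.75%, where the medians were 1.56% in D1 and 1.63% in D2 cells. Of these, 8 of 9 D1 and 12 of 12 D2 cells were gene-rich, so this largely repeats the test in gene-rich cells. Their median number of genes with a read was 6372 in D1 and 7357 in D2 cells, so a remaining difference in gene number is not excluded. Whether the D2 cells held more corticofugal neurons cannot be told, since intratelencephalic and upper-layer markers, which would then be higher in D1 cells, lay at percentile 84.6 in knockout and 65 in wild-type cells. The side label, which splits the cells as their kind does, and the depth of the recorded layer, which no label gives, stay open and untested.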
